A study of Mus musculus with 14 samples.

How the data were processed

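The data are gene expression arrays of mouse colon tumours and control epithelium, 14 samples in 4 groups, with 1 array per sample. The deposited intensities are GCRMA values (background correction, normalization between arrays and summary per probe set, named in the submitters' processing notes), on a linear scale and rounded to whole numbers from 2 to 31599. The authors also deposited fold changes, given as an absolute ratio with a direction word, for tumour against control in each model. The corrected p-values deposited by the authors come with them, and their test and correction are not stated. The array design and the genome build are not given in the sources used here. The intensities are held by 2 deposited tables, which differed in 0 cells, and 0 sample columns were left unmapped.

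The comparisons, gene lists, rule for naming genes and alternatives were set before the data were examined, except where stated. That design assumed log2 values. The values turned out to be linear, so log2 was taken first. Groups came from the sample labels, and the replicates are separate mice or pools of mice. Of 22690 probe sets, 21204 had 1 gene symbol, 831 several and 655 none, and the last 2 kinds were left out of the gene tests. Symbols were brought up to date with a RefSeq gene table, which changed the symbol of 3605 probe sets and left 722 unmatched as deposited. For 72 probe sets the deposited name is in use for another gene and was kept. Each of 13150 genes was represented by its probe set with the highest mean, which mattered for 5066 genes with several. Genes with a log2 intensity above 4 (linear 16) in at least 2 samples were tested, 8065 in all, which left out 5085. Values at or below 16 were treated as background. Median intensities per array were 15 to 18, and the number of arrays limits the precision. Log2 intensities correlated within groups with r from 0.9268 to 0.9912.

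A linear model with 1 mean per group was fitted to all 14 samples with limma 3.58.1 in R 4.3.3, with moderated variances (10 residual and 3.07 prior degrees of freedom) and 2-sided tests. The 5 comparisons were tumour against control in each model, the difference between these effects, tumour against tumour and control against control. P-values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. Gene lists were tested with camera when they had at least 5 tested members, with a preset correlation of 0.01, and also with an estimated correlation and with fry. The neutrophil, T cell, B and plasma cell, glial and erythrocyte lists were too small. Adjusted p-values of lists are over the 21 lists. Where the mean of 1 group was at background, the fold was computed with that group's samples at the higher of 16 and their own value, and is given as a lower bound. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

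Genes were named by a fixed rule. For the first 3 comparisons it takes the 6 highest and 6 lowest log2 fold changes past the threshold, for the first 2 of them without overlap between samples, then 4 each way between tumours and 3 each way between controls. From each list it takes up to 4 members with the largest change past the threshold, or up to 2 with the smallest adjusted p where fewer than 2 pass. It always takes Ereg, Areg, Egfr, Apc, Axin2, Lgr5, Myc, Ptgs2, Il6, Il11 and Tnf, and it passes over unnamed and predicted transcripts.

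The pipeline was tested on simulated data with 200 changed genes among 8065, in 10 simulations. At a log2 change of 1 it recovered 50.9% in the CAC comparison, 66.8% in the sporadic comparison, 23% for the difference, 71.8% between tumours and 46.1% between controls. At a log2 change of 2 it recovered 82.4% to 94.4%. Of the calls 4.7% to 6.1% were false at a change of 1 and 4.5% to 5.2% at a change of 2. In the data 3775 genes passed in the CAC comparison and 4901 in the sporadic comparison, far more than the 200 simulated. Recovery after adjustment depends on the share of changed genes, so these rates need not hold for the data. Camera was tested in the CAC comparison only, with lists of 20 genes and a log2 shift of 1, where it called 10 of 10 shifted lists and 1 of 190 unshifted lists. The simulated genes were independent, so this cannot show how often camera calls lists of correlated genes falsely. In the data the estimated correlation was 0.461 for cell cycle and 0.641 for extracellular matrix genes.

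The alternatives were a stricter threshold of 0.01, a log2 fold change of at least 1, quantile normalization, median centring, no intensity filter, a filter above 6, the mean of all probe sets of a gene, trended and robust variances, array weights, the replicate number as a block, fits of the compared groups only, and each sample left out in turn. Leaving out CAC tumours 1 and 4 together was added after the data were seen. The samples were also split in other ways, all 56 splits of the sporadic samples and 100 drawn of 126 for the tumours. With 1 sample left in a group, that sample is assumed to vary like the other groups.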

Results

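Total RNA from the distal colon of male mice was labelled as biotinylated cRNA and profiled on 14 expression arrays, 1 per sample. Colitis-associated tumours (CAC, 4 tumours from 4 mice) arose in C57BL/6J mice given the carcinogen azoxymethane at 10 mg/kg and then 3 cycles of dextran sodium sulfate (DSS, 2.5% w/v), a polymer that injures the colon epithelium and causes colitis. Sporadic tumours (5 tumours from 5 mice) came from ApcMin/+ mice, which carry a germline truncating mutation of the Wnt pathway suppressor Apc. Each model had its own control of tumour-free distal epithelium, 2 pools of 5 mice for CAC and 3 pools of 4 mice for the sporadic model. Tumours were whole pieces, while the controls were epithelium released from the tissue in a chelating buffer, in which the tumours were also incubated. Tumour and preparation therefore cannot be told apart wherever tumours are compared with controls, for genes that rise or fall. The labels do not say whether the CAC control mice received azoxymethane or DSS. They give the sporadic control mice the strain name of the ApcMin/+ mice and no separate genotype, so whether these controls carried the mutation is not stated. All CAC samples belonged to experimental block 1 and all sporadic samples to block 2.

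Values were array intensities for 22690 probe sets, and 8065 genes were tested. The median intensity per array lay between 15 and 18, close to background, and 48.95% to 50.92% of probe sets were above an intensity of 16. The number of arrays limits the precision of every comparison. Errors given with log2 fold changes are standard errors (SE) from 1 limma fit over all 14 samples, and p-values are adjusted over all genes tested unless stated otherwise. A fold written as "at least" had 1 group with its mean at background intensity. Log2 fold changes and list medians are fitted values, which are no bounds for such genes. The first principal component held 71.1% of the variance and separated the 9 tumours (25.48 to 64.57) from the 5 controls (-86.79 to -79.79). The next held 10% and separated all CAC samples (16.56 to 33.37) from all sporadic samples (-30.55 to -10.29). On component 3, with 4.6%, CAC tumour 1 lay at 50.12 and the other samples between -16.87 and 9.02.

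**Figure D1:**
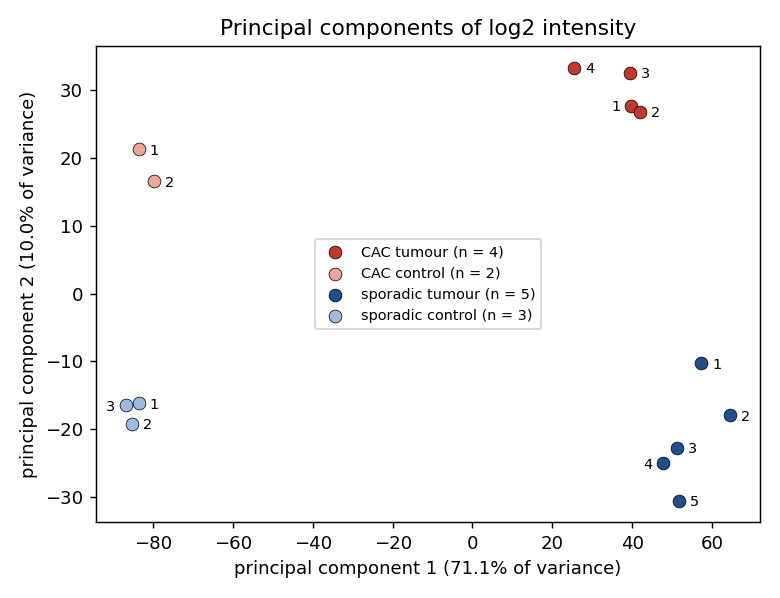
Each point is 1 sample on principal components 1 and 2 of log2 intensity over the 8065 genes tested, coloured by group and numbered by replicate. Component 1 separates tumours from control epithelium and component 2 separates the 2 models, which coincide with the 2 experimental blocks.

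The first comparison set CAC tumours (n = 4) against CAC control epithelium (n = 2 pools). Wnt target genes were higher in the tumours, with 21 of 23 measured members up, 0 down and 2 not past the threshold. Axin2, a feedback inhibitor induced by Wnt signalling, rose 13.3-fold (log2 fold change 3.73 ± 0.30, adjusted p = 7.38e-07). The stem cell marker Lgr5 rose at least 11.1-fold (4.66 ± 0.79), Myc rose 4.34-fold (2.12 ± 0.19), and the secreted Wnt inhibitors Notum and Wif1 rose at least 46.1-fold (6.36 ± 0.39) and at least 61.1-fold (6.18 ± 0.39). Transcripts of mature absorptive colonocytes were lower, with 0 of 28 up, 24 down and 4 not past the threshold. The carbonic anhydrase Car4 fell by 8.91 ± 0.82 on the log2 scale, and without CAC tumour 4 it was at least 723-fold lower. Of the others, the chloride-bicarbonate exchanger Slc26a3 was at least 230-fold lower (-8.74 ± 0.40) and the water channel Aqp8 was at least 116-fold lower (-8.48 ± 0.26). Apc itself differed by 0.14 ± 0.17 (adjusted p = 0.536). In all, 3775 of 8065 genes passed the threshold, 2150 higher and 1625 lower in tumours, and 2256 of them differed at least 2-fold. The larger direction depended on the scaling, with 1880 higher and 1968 lower after quantile normalization and 1859 higher and 1903 lower with each array centred on its median.

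CAC tumours also carried lower levels of other epithelial programmes. Of 8 enteroendocrine genes 6 fell, 0 rose and 2 did not pass, among them the hormones Insl5 (at least 16.2-fold lower, -5.21 ± 0.57) and Gcg (at least 12.1-fold lower, -4.70 ± 0.14). Of 19 genes of fatty acid oxidation and ketogenesis 16 fell, 0 rose and 3 did not pass, including Cpt1a, which imports fatty acids into mitochondria (-2.16 ± 0.20). Of 12 goblet cell genes 9 fell, 0 rose and 3 did not pass, with 1 higher and 9 lower adjusted over the list alone. Among them were Klk1 (-4.73 ± 0.73), which was 26.5-fold lower and 44.4-fold without CAC tumour 4, and the mucus protein gene Fcgbp (-3.40 ± 0.75), 10.5-fold lower and 6.48-fold without CAC tumour 1. Proliferation genes were higher, with 23 of 26 cell cycle genes up, 0 down and 3 not past the threshold, such as Rrm2 (2.98 ± 0.42), Top2a (2.49 ± 0.35) and Mcm4 (2.48 ± 0.36). Rrm2 was 7.87-fold higher, 4.58-fold without CAC control 1 and 13.5-fold without CAC control 2. Of 7 Paneth cell and antimicrobial genes 6 rose and 1 did not pass. Lysozyme Lyz1 rose 355-fold (8.47 ± 0.32), the protease Mmp7 153-fold (7.26 ± 0.28) and the phospholipase Pla2g2a 141-fold (7.14 ± 0.37). The CAC control pools were close to background for Mmp7 (17 and 16) and Pla2g2a (12 and 26), which limits these 2 folds. Residual colonocyte transcripts stood out in CAC tumour 4, where the Car4 intensity was 181 against 11 to 13 in the other CAC tumours.

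Stromal and immune transcripts moved with the CAC tumours, which were whole pieces set against released epithelium. This difference in preparation cannot be told apart from a tumour effect here. Of the marker genes, 9 of 11 for fibroblasts rose (10 adjusted over the list alone), as did 10 of 11 for macrophages, 4 of 6 for endothelium and 3 of 6 for smooth muscle, and 0 of these fell. Of the smooth muscle calls, that of Actg2 ended with 5 of 6 samples left out in turn, up to an adjusted p of 0.208 without CAC control 2. Vim rose 35.5-fold (5.15 ± 0.33), the complement gene C1qa at least 19.7-fold (6.01 ± 0.59), the endothelial gene Plvap at least 10.6-fold (3.76 ± 0.45) and Acta2 at least 46.1-fold (5.53 ± 0.51). With these markers, 16 of 19 extracellular matrix genes rose and 3 did not pass, led by Fn1 (at least 52.8-fold, 7.03 ± 0.37). Of 16 matrix proteases and inhibitors 13 rose and 3 did not pass, such as Mmp10 (at least 50.7-fold, 7.08 ± 0.94) and Mmp13 (at least 37.5-fold, 6.64 ± 1.28). Of 16 inflammatory mediators 11 rose, 0 fell and 5 did not pass, with 12 higher and 1 lower adjusted over the list alone. The neutrophil proteins S100a9 and S100a8 rose at least 104-fold (6.85 ± 0.97) and at least 55.4-fold (6.79 ± 1.10), the chemokine Cxcl2 at least 13.3-fold (5.41 ± 0.78), and Ptgs2, the inducible cyclooxygenase, at least 3.91-fold (3.38 ± 0.35). The bounds of S100a9 and S100a8 were 64.3-fold and 29-fold without CAC tumour 1 and 202-fold and 114-fold without CAC tumour 4, and that of Cxcl2 was 20.3-fold without CAC tumour 4. Tnf (0.89 ± 0.59, adjusted p = 0.238) and Il11 (2.38 ± 1.03, adjusted p = 0.0734) did not pass. Il6 was below the intensity filter, with 69 in CAC tumour 1 and 10 or less in the other samples. The plasma cell gene Jchain rose at least 70.4-fold (8.34 ± 0.90).

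Of 10 EGFR ligands and receptors 2 rose, 2 fell and 6 did not pass in CAC tumours. The ligand Ereg rose at least 6.06-fold (4.04 ± 0.68) and Btc at least 2.77-fold (1.77 ± 0.41), while the receptors Erbb2 and Erbb3 fell by 1.21 ± 0.22 and 1.20 ± 0.22. The ligand Areg (-1.25 ± 0.66, adjusted p = 0.14) and Egfr (-0.39 ± 0.25, adjusted p = 0.228) did not pass. Of 13 ERK feedback targets 8 rose and 1 fell, with Ier3 (4.74 ± 0.47) and Phlda1 (3.66 ± 0.39) the farthest up. Ier3 was 26.8-fold higher, 16.3-fold without CAC control 1 and 43.9-fold without CAC control 2. Of 16 p53 targets 5 rose and 5 fell (6 and 5 adjusted over the list alone), from Phlda3 (at least 9.53-fold up, 4.23 ± 0.24) to Gadd45a (-1.99 ± 0.25). Of 19 interferon response genes 2 rose and 1 fell (1 and 0 adjusted over the list alone), and Ifit2 rose at least 5.27-fold (2.94 ± 0.51). The calls of Usp18, higher, and Oas1a, lower, each ended with 4 of 6 samples left out, up to adjusted p = 0.128 without CAC control 2 and 0.126 without CAC control 1. Of 7 squamous epithelium genes 3 rose, among them Krt14 (at least 15.1-fold, 5.11 ± 0.90), whose intensity was 1739 in CAC tumour 1 and 114 to 144 in the other CAC tumours. Without CAC tumour 1 the Krt14 bound was 7.83-fold. The calls of Krt6a and Sprr1a ended with 2 and 4 of 6 samples left out, up to adjusted p = 0.13 without CAC control 1 and 0.252 without CAC control 2. Of 6 mast cell markers 2 rose, the proteases Mcpt1 and Mcpt2. The Mcpt1 call ended without CAC control 1 (adjusted p = 0.0859) or 2 (0.081), and the Mcpt2 call with 4 of 6 samples left out, up to 0.0982 without CAC control 2. Of 5 MHC class II genes 0 rose and Ctss fell by 1.53 ± 0.36. Neutrophil, T cell, plasma cell, glial and erythrocyte lists had fewer than 5 measured members and were not tested as lists. Of their other members, the T cell gene Cd8b1 rose (0.61 ± 0.20, adjusted p = 0.0208), a call that ended with 3 of 6 samples left out, up to adjusted p = 0.119 without CAC control 1, and in a fit of the compared groups only (0.0523). The neutrophil gene Csf3r (adjusted p = 0.44), the T cell genes Lck (0.554) and Thy1 (0.674) and the plasma cell list genes Xbp1 (0.061) and Ighm (0.803) did not pass. The haemoglobin gene Hba-a1 was 3.09-fold lower (-1.63 ± 0.48), a call that ended without CAC control 1 (adjusted p = 0.0819) or 2 (adjusted p = 0.0625), and the glial gene Gpm6b did not pass (1.06 ± 0.49, adjusted p = 0.0966).

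As sets against all other genes, 13 of the 21 lists passed camera in this comparison with its preset correlation. Colonocyte differentiation (median log2 fold change -3.04, camera adjusted p = 9.96e-13), Wnt targets (3.54, 9.00e-11), fatty acid oxidation (-1.39, 1.74e-07) and enteroendocrine cells (-2.56, 6.56e-05) also passed with an estimated correlation, at adjusted p = 0.0467, 0.0312, 0.0149 and 0.0149. The calls for cell cycle (median 1.71), extracellular matrix (3.87), matrix proteases (2.91), macrophage (3.34), fibroblast (3.83), inflammatory mediators (3.98), Paneth and antimicrobial (7.14), goblet cell (-1.53) and endothelial cell (2.41) did not. For these 9 lists, in that order, adjusted p = 0.258, 0.279, 0.0785, 0.23, 0.271, 0.0785, 0.0654, 0.314 and 0.311 with an estimated correlation. The goblet cell call also ended without the intensity filter (adjusted p = 0.145). Smooth muscle (median 1.87, adjusted p = 0.0529), ERK feedback (1.15, 0.0529), squamous epithelium (2.38, 0.317), EGFR ligands and receptors (-0.44, 0.43), mast cell (0.26, 0.595), MHC class II (1.78, 0.859), interferon response (0.31, 0.906) and p53 targets (0.02, 0.961) did not pass camera. For the EGFR list the median and the test were negative and the mean was positive (0.015). Mmp7 is in 3 lists and the fibrillar collagens are in 2, so the lists are not independent. The lists were scored with adjusted p over all genes, and counts adjusted over the list alone are the same where no second count is given.

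**Figure D2:**
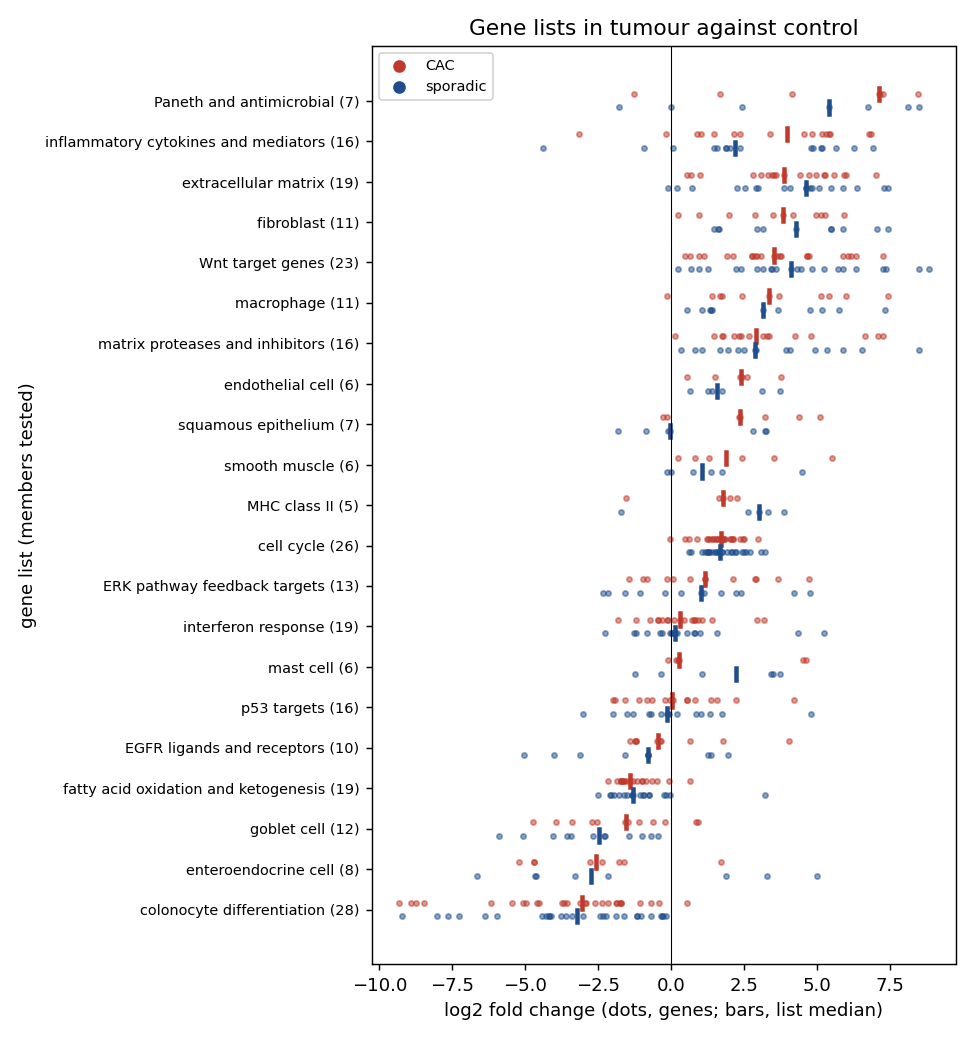
Log2 fold change of tumour over control for the members of the 21 gene lists tested, in CAC (red) and the sporadic model (blue), with dots for genes and bars for list medians. The medians of colonocyte, enteroendocrine and goblet cell genes lie to the left of 0 in both models, and those of Wnt target, matrix and macrophage genes to the right.

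The second comparison set sporadic ApcMin/+ tumours (n = 5) against sporadic control epithelium (n = 3 pools). Wnt target genes were again higher, with 21 of 23 up, 0 down and 2 not past the threshold. Axin2 rose 19.9-fold (4.32 ± 0.26, adjusted p = 1.58e-08), Lgr5 at least 5.24-fold (3.15 ± 0.67), Myc 4.71-fold (2.23 ± 0.16) and the membrane Wnt inhibitor Apcdd1 at least 219-fold (8.84 ± 0.57). Of 28 colonocyte genes 0 rose, 23 fell and 5 did not pass, with Car4 at least 425-fold lower (-9.21 ± 0.69), Slc26a3 at least 114-fold lower (-8.03 ± 0.34) and Aqp8 at least 49.5-fold lower (-7.25 ± 0.22). The matrix inhibitor of calcification Mgp rose at least 478-fold (10.58 ± 0.34). Apc was 1.60-fold higher (0.68 ± 0.14, adjusted p = 0.000983). In all, 4901 of 8065 genes passed, 2632 higher and 2269 lower, and 2746 of them differed at least 2-fold. With each array centred on its median the same comparison gave 1944 higher and 3116 lower, as centring moved the median log2 fold change of all genes from 0.07 to -0.20, and quantile normalization gave 2419 higher and 2581 lower. That setting moved the median of all genes from 0.10 to -0.01 in the CAC comparison, where quantile normalization gave -0.02.

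Sporadic tumours had 25 of 26 cell cycle genes up (26 adjusted over the list alone), including Rrm2 (3.21 ± 0.36) and Top2a (3.08 ± 0.30). Of 12 goblet cell genes 10 fell and 2 did not pass, such as Klk1 (-5.90 ± 0.62) and the secretory lineage factor Atoh1 (at least 19.7-fold lower, -5.08 ± 0.61). Of 8 enteroendocrine genes 5 fell, with Insl5 at least 31.7-fold lower (-6.66 ± 0.48), and 3 rose, with the islet factor Isl1 at least 11-fold higher (5.01 ± 1.13). Of 19 fatty acid oxidation genes 15 fell, such as the ketone body enzyme Bdh1 (-2.51 ± 0.22), and 1 rose, Pdk4 (at least 3.71-fold, 3.23 ± 0.73). Of 7 Paneth and antimicrobial genes 5 rose, 1 fell and 1 did not pass, with Mmp7 at least 137-fold (8.51 ± 0.24) and Lyz1 276-fold (8.11 ± 0.27) up.

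Stromal and immune markers moved with the sporadic tumours too, again whole pieces against released epithelium, so the same limit holds. Of the markers, 10 of 11 rose for fibroblasts (11 adjusted over the list alone), 10 of 11 for macrophages, 5 of 6 for endothelium and 3 of 6 for smooth muscle, with 0 lower. The Esam call ended with 4 of 8 samples left out, up to adjusted p = 0.087 without sporadic control 3, and the Tagln call with 3, up to 0.0579 without sporadic control 3. Vim rose 134-fold (7.06 ± 0.28), C1qa at least 13.4-fold (5.74 ± 0.50), Plvap at least 8.83-fold (3.74 ± 0.38) and Acta2 at least 20.9-fold (4.48 ± 0.43). With them, 16 of 19 extracellular matrix genes (Col3a1 at least 125-fold, 7.43 ± 0.49) and 14 of 16 matrix proteases and inhibitors (Plat 92.9-fold, 6.54 ± 0.45) rose, and 0 fell. Of 16 inflammatory mediators 12 rose, 2 fell and 2 did not pass. S100a9 rose at least 68.5-fold (6.93 ± 0.82), Il1b at least 16.4-fold (5.17 ± 0.48), Tnf 4.02-fold (2.01 ± 0.50) and Ptgs2 at least 1.15-fold (1.48 ± 0.29, adjusted p = 0.000664), while Il11 did not pass (1.58 ± 0.87, adjusted p = 0.132). Of 5 MHC class II genes 4 rose, led by Cd74 (14.7-fold, 3.87 ± 0.81), and 1 fell. The calls of H2-Ab1 and H2-Eb1 ended with 2 and 4 of 8 samples left out, up to adjusted p = 0.0584 without sporadic control 3 and 0.133 without sporadic control 1. Of 6 mast cell markers 4 rose, such as Hdc (at least 6.28-fold, 3.48 ± 1.00), and Kit was lower, at least 1.93-fold (-1.23 ± 0.19). The Mcpt1 and Mcpt2 calls ended with 3 and 2 of 8 samples left out, up to adjusted p = 0.0636 and 0.0512 without sporadic control 3. The bound of Hdc was 11.5-fold without sporadic tumour 1 and 3.74-fold without sporadic tumour 2. Jchain rose at least 4.98-fold (4.73 ± 0.76), or 7.7-fold without sporadic tumour 3, Hba-a1 3.20-fold (1.68 ± 0.41) and Gpm6b at least 2.55-fold (2.43 ± 0.42). Lck and Thy1 passed the threshold, but their mean intensities of 12.7 and 15.3 in the tumours were at background, so no fold is given. Xbp1 fell by 0.53 ± 0.15, a call that ended without sporadic control 2 (adjusted p = 0.0603), and Cd8b1 (adjusted p = 0.816), Csf3r (0.949) and Ighm (0.826) did not pass.

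EGFR ligands moved apart in sporadic tumours. Of 10 EGFR ligands and receptors 2 rose, 7 fell and 1 did not pass (3 higher and 7 lower adjusted over the list alone). Areg fell by 5.03 ± 0.56 on the log2 scale (32.6-fold, adjusted p = 5.17e-06) and Hbegf by 4.02 ± 0.49, whereas Tgfa rose 3.88-fold (1.96 ± 0.30) and Ereg did not pass (1.38 ± 0.57, adjusted p = 0.0509). Egfr fell by 0.79 ± 0.21. Of 13 ERK feedback targets 7 rose and 2 fell (7 and 3 adjusted over the list alone), with Etv5 at least 12.6-fold up (4.78 ± 0.74) and Fos down (-2.33 ± 0.61). Of 16 p53 targets 5 rose and 5 fell, from Phlda3 (at least 12.5-fold up, 4.78 ± 0.20) to Btg2 (-3.03 ± 0.60). Of 19 interferon response genes 3 rose and 3 fell (3 and 2 adjusted over the list alone), with Usp18 (at least 14.1-fold, 5.24 ± 0.87) and Ifit2 (at least 12.1-fold, 4.34 ± 0.43) the farthest up. Of 7 squamous epithelium genes 2 rose and 2 fell (2 and 1 adjusted over the list alone), Krt14 at least 5.04-fold up (3.27 ± 0.76) and Krt10 down (-0.85 ± 0.21). The calls of Krt6a and Sprr1a ended with 5 and 7 of 8 samples left out, up to adjusted p = 0.0898 without sporadic control 1 and 0.141 without sporadic control 3.

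In the sporadic comparison 13 of 21 lists passed camera with its preset correlation and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05, while fry, which tests whether a list's genes move 1 way, passed 16. The 13 were Wnt targets (median log2 fold change 4.11, camera adjusted p = 4.15e-10), colonocyte differentiation (-3.21, 2.07e-09), cell cycle (1.68, 8.80e-08), extracellular matrix (4.61, 1.41e-05), fatty acid oxidation (-1.30, 1.61e-05), matrix proteases (2.88, 1.61e-05), fibroblast (4.27, 5.47e-05), goblet cell (-2.48, 0.00014), macrophage (3.15, 0.000169), inflammatory mediators (2.18, 0.00484), Paneth and antimicrobial (5.40, 0.00931), enteroendocrine cell (-2.73, 0.0224) and endothelial cell (1.58, 0.0259). In the same order, adjusted p = 0.052, 0.125, 0.221, 0.315, 0.052, 0.125, 0.221, 0.21, 0.225, 0.163, 0.163, 0.125 and 0.34 with an estimated correlation. The enteroendocrine call also ended with median centring (adjusted p = 0.083) and with a filter above a log2 intensity of 6 (adjusted p = 0.0769). EGFR ligands and receptors (median -0.78, adjusted p = 0.129), ERK feedback (1.01, 0.181), smooth muscle (1.06, 0.215), MHC class II (3.00, 0.45), mast cell (2.24, 0.73), p53 targets (-0.14, 0.837), interferon response (0.14, 0.868) and squamous epithelium (-0.03, 0.926) did not pass. For squamous epithelium the median was negative and the mean (0.93) and the test positive, and for p53 targets the median and camera were negative and fry positive.

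The tumour effects of the 2 models were set side by side, each against its own controls, with no sample in common. Of 8065 genes, 1691 were higher in both models, against 702 for independent lists of these sizes, and 1394 were lower in both, against 457. Among the 3106 genes called in both, 99.32% had the same direction, and 21 genes went opposite ways, 11 higher and 10 lower in CAC. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.89 and Spearman's rho = 0.84. Both models set whole tumour pieces against released epithelium, so the overlap cannot tell a shared tumour effect from this shared difference in preparation. The counts for independent lists do not allow for it. Mgp, Mmp7, Lyz1 and Wif1 were among the genes higher in both, and Car4, Slc26a3, Cyp2c55, Aqp8 and Ces2a among those lower in both. Without CAC tumours 1 and 4, a setting chosen after the data were seen, 2951 genes were called in the same direction in both models, against 3085 with all samples.

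**Figure D3:**
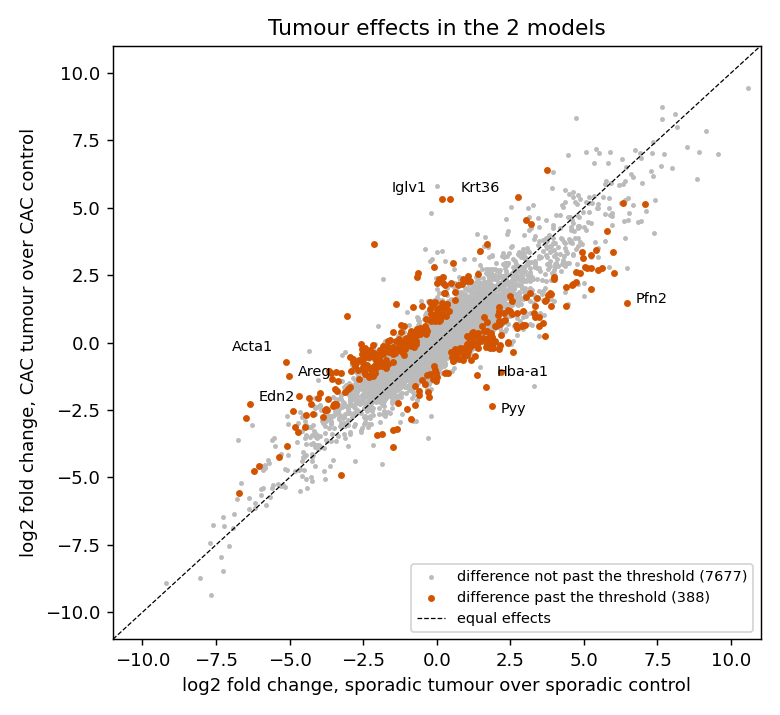
Log2 fold change of CAC tumours over CAC controls (vertical axis) against that of sporadic tumours over sporadic controls (horizontal axis) for the 8065 genes tested. Orange points are the 388 genes whose effect differed between the models, and the dashed line marks equal effects.

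The difference between the tumour effects was then tested directly, as the CAC effect minus the sporadic effect (n = 4, 2, 5 and 3 samples). A log2 shift common to all samples of a block cancels from it only where tumours and controls are above background. Dkk2, Ptgs2 and Iglv1 were at background in every control pool, with intensities of 5 to 9. For these genes a block shift between the tumours would remain in the difference. The EGFR ligand Areg was 3.78 ± 0.87 higher in this difference (adjusted p = 0.0256). It was 32.6-fold lower in sporadic tumours than in their controls and 2.38-fold lower, not past the threshold, in CAC tumours. The distance lay between the controls, with Areg intensities of 352 and 356 in the CAC pools and 2024 to 3943 in the sporadic pools. In the tumours they were 115 to 205 and 41 to 297. Ptgs2 was also higher in the difference (1.90 ± 0.45, adjusted p = 0.0312), as was Spdef, a factor of goblet cell maturation (2.32 ± 0.54, adjusted p = 0.0274). The Wnt inhibitor gene Dkk2 (-2.45 ± 0.64, adjusted p = 0.0442) and the ligand gene Wnt6 (-2.29 ± 0.54, adjusted p = 0.0274) were lower, and so was the hormone gene Pyy (-4.22 ± 0.86, adjusted p = 0.0148), whose log2 fold change was -2.35 in CAC and 1.87 in sporadic tumours. The difference for Ereg was 2.66 ± 0.88 (adjusted p = 0.102), for Axin2 -0.58 ± 0.40 (adjusted p = 0.405), for Lgr5 1.51 ± 1.03 (adjusted p = 0.407), for Myc -0.12 ± 0.25 (adjusted p = 0.817) and for Tnf -1.12 ± 0.77 (adjusted p = 0.413), so these did not pass. Leaving out single samples ended several of these calls, most often leaving out a CAC control pool. Without CAC control 1 the adjusted p was 0.0893 for Areg, 0.0988 for Ptgs2, 0.0854 for Spdef, 0.124 for Dkk2, 0.0708 for Wnt6 and 0.0567 for Pyy. Without CAC control 2 it was 0.0806, 0.0916, 0.0916, 0.118, 0.11 and 0.0609, in the same order. Of the 14 samples left out in turn, 4 ended the call for Areg, 7 for Ptgs2, 5 for Spdef, 12 for Dkk2, 5 for Wnt6 and 2 for Pyy, and for Areg the others were sporadic control 2 (adjusted p = 0.0633) and 3 (0.0623). Without both CAC tumours 1 and 4, a setting chosen after the data were seen, the adjusted p was 0.0695 for Areg, 0.0681 for Ptgs2, 0.0585 for Spdef and 0.073 for Dkk2. The Dkk2 call also ended with quantile normalization (0.0541) and without the intensity filter (0.0586). With the replicate number as a block, the calls for Dkk2 (0.078) and Pyy (0.0669) ended.

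The highest differences among the genes named by the rule were Iglv1, an immunoglobulin light chain gene (5.15 ± 0.85, adjusted p = 0.00553), the hair keratin Krt36 (4.86 ± 0.86, adjusted p = 0.00816), the skeletal actin Acta1 (4.40 ± 0.69, adjusted p = 0.00483) and the endothelin gene Edn2 (4.07 ± 0.57, adjusted p = 0.00253). These 4 calls held with every sample left out in turn. Without CAC control 1 the difference was 5.36 for Acta1 and 4.75 for Edn2, without CAC control 2 it was 3.45 and 3.39, and for Iglv1 it was 5.80 without CAC tumour 1. For Iglv1 the distance lay between the tumours, 87 to 823 in CAC and 7 to 16 in sporadic tumours. For Acta1 and Edn2 it lay between the controls, and Edn2 intensity was 26 and 67 in the CAC control pools and 981 to 1464 in the sporadic ones. Among the lower ones, beside Pyy, were the actin regulator Pfn2 (-4.99 ± 1.01, adjusted p = 0.0144), which ended without CAC control 1 (adjusted p = 0.0684) and was -5.59 without CAC tumour 3, and Lmo2 (-3.45 ± 0.70), which ended without CAC control 1 (adjusted p = 0.056) or 2 (adjusted p = 0.0609) and with the replicate block (adjusted p = 0.0512). In all, 388 genes passed, 230 higher and 158 lower, and 323 of them differed at least 2-fold. Median centring gave 639 genes, 502 higher and 137 lower, as it moved the median of all genes from 0.05 to 0.21. With the replicate number as a block 206 genes passed. The count was 170 without CAC control 1, 230 without CAC control 2, 254 without sporadic control 1, 87 at an adjusted p of 0.01 and 1014 without the intensity filter.

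Among the 21 lists, camera with its preset correlation passed goblet cell genes (median 0.82, adjusted p = 0.0408) and Wnt targets (median -0.58, adjusted p = 0.0312) in the difference, and neither with an estimated correlation (adjusted p = 0.902 for both). Of the goblet cell genes 1 of 12 passed, higher, and of the Wnt targets 2 of 23 passed, both lower, with 2 and 4 adjusted over the list alone. With an estimated correlation 0 lists passed and 0 had an unadjusted p under 0.05. Fry also passed 0 lists, with 3 at an unadjusted p under 0.05. The goblet cell call ended with each of 7 samples left out, up to an adjusted p of 0.137 without CAC control 1, and the Wnt target call with each of 3, at 0.0641 without CAC control 1, 0.0553 without sporadic control 2 and 0.0568 without sporadic control 3. The goblet cell call also ended without the intensity filter (0.27), with median centring (0.109), with a filter above 6 (0.0955), with array weights (0.0688) and with the mean of all probe sets (0.063). The Wnt target call also ended without the intensity filter (0.441) and with quantile normalization (0.0524). Without CAC tumours 1 and 4, a setting chosen after the data were seen, both calls ended (0.0749 for goblet cell genes and 0.0698 for Wnt targets). The EGFR list had 1 of 10 members past the threshold, and 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.358). The other 18 lists had camera adjusted p from 0.0992 to 0.845. For endothelial cells the median (0.32) and mean were positive and the test negative, and for mast cells the median (0.71) and test were positive and the mean negative (-0.06).

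**Figure D4:**
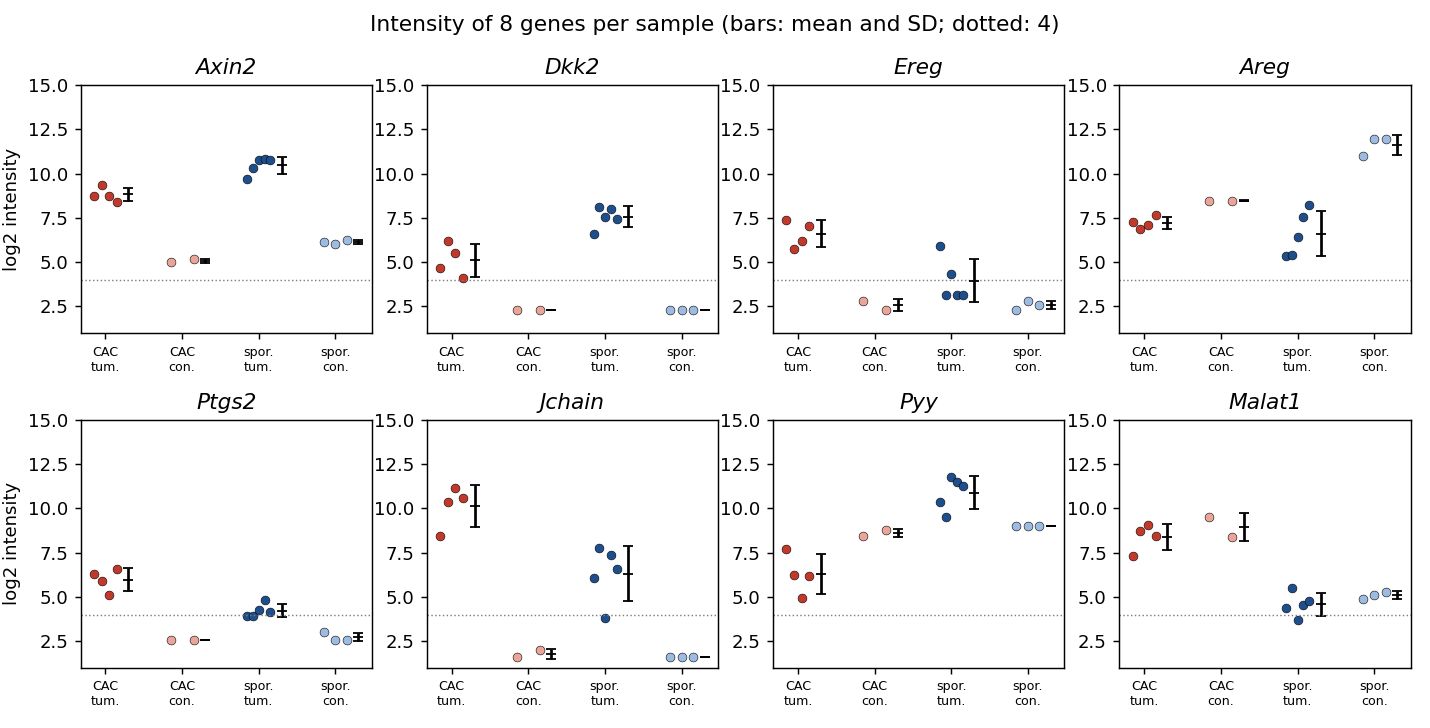
Log2 intensity of 8 genes in each of the 14 samples, with group mean and standard deviation as bars beside the points and a dotted line at 4, the background limit. Areg was highest in the 3 sporadic control pools, and Malat1 separated both CAC groups from both sporadic groups.

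CAC tumours (n = 4) and sporadic tumours (n = 5) were also compared with each other, although model and experimental block cannot be told apart here. Jchain was 14.1-fold higher in CAC tumours (3.82 ± 0.70, adjusted p = 0.00205), while the other measured genes of the plasma cell list, Xbp1 (0.39, adjusted p = 0.0642) and Ighm (1.34, adjusted p = 0.0723), did not pass. Iglv1, which is outside that list, was at least 21.2-fold higher (5.36 ± 0.50, adjusted p = 2.89e-05), or 33.4-fold without CAC tumour 1. Jchain was 9.14-fold higher without sporadic tumour 3, which was at background. Ereg was at least 4.45-fold (2.65 ± 0.52, adjusted p = 0.00319) and Ptgs2 3.39-fold higher (1.76 ± 0.27, adjusted p = 0.000657). Of 23 Wnt targets 12 were lower in CAC tumours and 0 higher (12 and 1 adjusted over the list alone), among them Axin2 (-1.64 ± 0.23), Dkk2 (-2.45 ± 0.38) and Wnt6 (-2.10 ± 0.32). Pyy was 24.3-fold lower (-4.60 ± 0.51) and the lipoxygenase Alox15 at least 5.84-fold higher (3.62 ± 0.75). Alox15 was at background in CAC tumour 1, and the bound was 12.3-fold without this tumour and 3.8-fold without CAC tumour 3. The long noncoding RNA Malat1 was 14-fold higher in CAC tumours (3.81 ± 0.39) and 14.5-fold higher in CAC than in sporadic controls (3.86 ± 0.53). Areg (0.62 ± 0.51, adjusted p = 0.41), Lgr5 (1.08 ± 0.61, adjusted p = 0.225) and Myc (-0.09 ± 0.15, adjusted p = 0.714) did not pass.

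Of 28 colonocyte genes 6 were higher in CAC than in sporadic tumours, 0 lower and 22 not past the threshold, such as Krt20 (2.29 ± 0.52) and the monocarboxylate transporter Slc16a1 (1.49 ± 0.16). Krt20 was 4.89-fold higher, and 7.57-fold without CAC tumour 1. Of 12 goblet cell genes 6 were higher and 0 lower (9 and 1 adjusted over the list alone), such as Spdef (at least 2.14-fold, 1.82 ± 0.32) and Sytl2 (1.14 ± 0.25). Of 7 Paneth and antimicrobial genes 3 were higher (5 adjusted over the list alone), Duoxa2, Reg3g and Itln1. Duoxa2 was at background in every sporadic tumour and in CAC tumours 1 and 4. The calls of Reg3g and Itln1 each ended with 7 of the 9 tumours left out, up to adjusted p = 0.127 without CAC tumour 1 and 0.14 without CAC tumour 3, and also without the intensity filter (0.102 and 0.0964). Of 8 enteroendocrine genes 0 were higher and 2 lower, Pyy and Nts (1 and 3 adjusted over the list alone). The Nts call ended with 6 of the 9 tumours left out, up to adjusted p = 0.0701 without sporadic tumour 4, without the intensity filter (0.0692) and without CAC tumours 1 and 4 (0.144). Of 11 macrophage markers 2 were higher, Mrc1 (1.24 ± 0.36) and C1qb (1.04 ± 0.31), whose calls ended with 6 and 5 of the 9 tumours left out, up to adjusted p = 0.0673 without CAC tumour 2 and 0.0855 without CAC tumour 3. Of 6 smooth muscle markers 3 were higher, Tagln, Cnn1 and Myh11, and Mylk was lower (-1.55 ± 0.23), with 5 and 1 adjusted over the list alone (median 1.29, camera adjusted p = 0.0696). The calls of the 3 higher ones ended with 5, 6 and 1 of the 9 tumours left out, up to adjusted p = 0.0882, 0.0888 and 0.0523 without CAC tumour 4. Camera passed 5 lists, goblet cell (median 1.08, adjusted p = 0.000493), colonocyte (0.48, 0.000493), Paneth and antimicrobial (0.83, 0.00702), macrophage (0.45, 0.0268) and Wnt targets (-0.84, 0.0268). In this order adjusted p = 0.621, 0.621, 0.586, 0.68 and 0.621 with an estimated correlation, where 0 lists passed and 1 had an unadjusted p under 0.05, and fry passed 3 lists. Without the intensity filter the macrophage and Paneth calls ended (adjusted p = 0.345 and 0.111), and with the mean of all probe sets the macrophage (0.0513) and Wnt target (0.0519) calls ended. Median, mean and test differed in sign for cell cycle, enteroendocrine, fatty acid oxidation, matrix protease and mast cell lists, none of which passed. The Wnt target call ended without sporadic tumour 5 (0.0656), and the macrophage call without CAC tumour 3 (0.0868) or sporadic tumour 3 (0.0761). In all, 1891 genes passed, 633 higher and 1258 lower in CAC tumours, and 656 of them differed at least 2-fold. Quantile normalization gave 805 higher and 1046 lower. Without CAC tumours 1 and 4, a setting chosen after the data were seen, 1311 genes passed, the call of Wnt targets ended (adjusted p = 0.0987) and so did 28 of the 59 calls of named genes, from 0.0517 for Reg3g to 0.392 for Ifit2. These included Sytl2 (0.0595), Mrc1 (0.0597), Myh11 (0.194), Tagln (0.271) and Cnn1 (0.282).

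The control epithelia of the 2 models differed as well (n = 2 and n = 3 pools). Edn2 was 27.6-fold lower in CAC controls (-4.79 ± 0.46, adjusted p = 4.53e-05), 44.3-fold without CAC control 1 and 17.2-fold without CAC control 2. Also lower were the neuronal activity gene Arc, at least 39.4-fold (-6.30 ± 1.06, adjusted p = 0.0022), and the matricellular gene Ccn1, 33.7-fold (-5.07 ± 0.59, adjusted p = 0.000218). Hba-a1 was 17.9-fold higher in CAC controls (4.16 ± 0.51, adjusted p = 0.000312), and so were fibroblast markers, with 4 of 11 up and 0 down, such as C3 (at least 5.62-fold, 3.18 ± 0.46) and Dcn (at least 3.91-fold, 3.05 ± 0.60, adjusted p = 0.071 without CAC control 1). The calls of the other 2 of these, Vim and Col3a1, ended with 4 and 2 of the 5 pools left out, up to adjusted p = 0.335 and 0.209 without CAC control 1. Of the EGFR ligands, Areg was 8.91-fold lower (-3.16 ± 0.70, adjusted p = 0.0105) and Hbegf 5.95-fold lower (-2.57 ± 0.61, adjusted p = 0.0143), while Tgfa was 2.57-fold higher (1.36 ± 0.38, adjusted p = 0.0297). The Tgfa call ended with 4 of the 5 pools left out, up to adjusted p = 0.354 without CAC control 1, where it was 1.56-fold, against 4.25-fold without CAC control 2. The Areg call ended without CAC control 1 (adjusted p = 0.0672) or 2 (adjusted p = 0.0518), and the Hbegf call without CAC control 2 (adjusted p = 0.117). The ERK feedback gene Phlda1 was 6.36-fold lower (-2.67 ± 0.41, adjusted p = 0.00126). Of 28 colonocyte genes 5 were higher and 0 lower (10 and 0 adjusted over the list alone), such as the transcription factor Cdx2 (at least 2.77-fold, 1.97 ± 0.33). Camera passed the colonocyte list (median 0.78, adjusted p = 7.99e-07) and the fibroblast list (0.65, 0.00232), and neither with an estimated correlation, where adjusted p = 0.838 and 0.854 and 1 list had an unadjusted p under 0.05. Fry passed 0 lists, with 1 at an unadjusted p under 0.05, and the fibroblast call ended without the intensity filter (adjusted p = 0.325). Median, mean and test differed in sign for fatty acid oxidation, mast cell and Wnt target lists, none of which passed. In all, 1224 genes passed, 301 higher and 923 lower, and quantile normalization gave 395 higher and 591 lower. The count was 514 without CAC control 1, 780 without CAC control 2, 801 without sporadic control 2, 415 at an adjusted p of 0.01 and 1919 without the intensity filter.

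The authors' deposited table holds fold changes and corrected p-values for both tumour comparisons. In the authors' deposited table Axin2 was 13.3-fold up in CAC (corrected p = 0.00213) and 20-fold up in sporadic tumours (corrected p = 0.000188), and Areg was 2.38-fold down in CAC (corrected p = 0.0248) and 32.7-fold down in sporadic tumours (corrected p = 0.00262). Areg in CAC did not pass in the limma fit. The authors' deposited table lists Ereg at 16.6-fold up in CAC (corrected p = 0.00858) and 2.47-fold up in sporadic tumours (corrected p = 0.165). Its log2 fold changes differed from those of the limma fit by a median of 0.0041 in CAC and 0.0036 in the sporadic comparison. Among the 8065 genes tested, the authors' deposited table has a corrected p under 0.05 for 2724 in CAC and 4752 in the sporadic comparison, of which 2555 and 4497 were also called in the same direction by limma.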

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

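The tests of an immediate-early response, of the array intensity scale, of squamous epithelium and of a brighter array were chosen after the results were seen.

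The tumour effect differed between the models for 388 genes. Of these, 60.8% differed more between the controls than between the tumours, against 53.2% of the other genes. Past the threshold were 223 between controls and 188 between tumours, 28 of them in both. For the 188 the tumours themselves differed, in a comparison where model and experimental block coincide. The 388 were chosen for a difference that includes the tumours, and 1891 of all 8065 genes differed between tumours. These counts therefore cannot decide on a difference between the control epithelia alone, which stays open. Immediate-early genes had a median log2 difference of -1.667 between CAC and sporadic controls. The SE of 0.283 for this list is a spread over the 19 genes, which are not replicates, and no error over samples. Of the 19 genes, 18 were lower in CAC controls and 6 were past the threshold. An immediate-early response in the sporadic controls may therefore contribute and stays open. Between the tumours the 19 genes had a median of -0.471, the same direction as between the controls. In the difference itself they had a median of 1.044, where with limma 0 passed and 2 had an unadjusted p under 0.05. A difference between the models, or a treatment of the CAC control mice that the labels leave open, was not tested.

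Between the tumours 1891 genes differed. Of 100 drawn splits of the 9 tumours only the real 1 gave as many, which argues against chance, though 100 splits cannot show a share below 1 in 100. The highest other gave 415, but the other splits mix the models, which widens the spread within groups and lowers their counts. Over the 1891 genes the slope of the control differences on the tumour differences was 0.337 (0.307 to 0.366 with samples left out), below that of a fully shared shift. The genes were chosen for their tumour difference, which itself lowers the slope, so it cannot settle how far a shift was shared. Between controls 74.8% had the same direction and 430 were also past the threshold in it. In the difference, where a shift shared by tumours and controls cancels for genes above background in both, 188 were past the threshold. After quantile normalization 86.8% were still called in the same direction, which argues against the array intensity scale. Model and experimental block cannot be told apart for these genes.

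CAC tumour 1 held squamous keratins, with Krt5 at an intensity of 1866 against 8 in each of the other CAC tumours and Krt13 at 2467 against 10 to 27. Brightness keeps the order of genes within an array, but the 7 keratins of the list rose there by a median of 40.7 percentile ranks (6.9 to 63.1). The SE of 7.2 is a spread over the keratins of 1 array. Krt14 and Krt6a had prompted the test. The others rose by 63.1 (Krt5), 55.4 (Krt13), 51.2 (Krt4), 39.3 (Krt1, at background) and 6.9 (Krt10), which argues against a brighter array. The 10 squamous markers that had not prompted the test lay a median log2 of 1.304 above the other CAC tumours (spread over the markers 1.034). Of them 4 lay at least 5 above, Krt5, Krt13, Krt4 and Sprr3. Another 4, Krt1, Ivl, Trp63 and Dsc3, were at background in all CAC tumours. These lower the median without telling either way, so it cannot decide. Several squamous transcripts were high in CAC tumour 1, and squamous epithelium in the sampled piece may be present but stays undecided. No other biological explanation was tested.

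In the sporadic comparison only the real split, 1 of 56, gave as many genes as the 4901 found. This argues against chance, though 56 splits cannot show a share below 1 in 56. The highest other split gave 52, but the other splits mix tumours with controls, which widens the spread within groups and lowers their counts.

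Of 349 groups of samples tested for the named genes, 24 had a sample far from the others by Dixon's ratio, and chance gives about 1 in 20. CAC tumour 4 was highest for Car4 (0.94), Creb3l1 (0.886), Cyp2c55 (1), Insl5 (0.905) and Slc26a3 (1), and lowest for Ppargc1a (0.902). CAC tumour 1 was highest for Birc5 (0.856) and Krt14 (0.914) and lowest for Ctss (0.844), Mcpt1 (0.834) and Mt4 (0.89). CAC tumour 3 was highest for Spred2 (0.979) and lowest for Timp3 (0.885). Sporadic tumour 1 was highest for Acta2 (0.733), Actg2 (0.885), Ces2a (0.91), Esam (0.766) and Myh11 (1), and lowest for Dach2 (0.731), Krt14 (0.776) and Mcpt1 (0.878). Sporadic tumour 2 was highest for Ifitm1 (0.825) and Tyrobp (0.805), and sporadic tumour 3 lowest for Ppargc1a (0.721).

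The named genes whose effect differed by the test of the difference, given as CAC minus sporadic log2 fold change, were Iglv1 (5.147), Krt36 (4.862), Acta1 (4.402), Edn2 (4.07), Tifa (4.056), Areg (3.778), Spdef (2.318), Plk2 (2.006), Phlda1 (1.941), Ptgs2 (1.898), Kit (1.13) and Xbp1 (0.973) on the higher side. On the lower side they were Pfn2 (-4.989), Pyy (-4.224), Lmo2 (-3.448), Dach2 (-3.431), Hba-a1 (-3.307), Wdfy1 (-3.299), Dkk2 (-2.452), Wnt6 (-2.295), Vim (-1.913), Mmp11 (-1.57), Timp2 (-1.562) and Spred2 (-1.264). Kit (13 to 15), Mmp11 (8 to 10) and Dach2 (6 to 14) were at background in all CAC samples, so their differences rest on the sporadic samples. With the mean of all probe sets the limma calls of Kit (0.502, adjusted p = 0.228) and Spred2 (-0.521, adjusted p = 0.113) ended. With every sample left out in turn only the calls of Iglv1, Krt36, Acta1 and Edn2 held. Without CAC control 1 the values were 5.36 for Acta1, 4.75 for Edn2 and 1.33 for Plk2, and without CAC control 2 they were 3.45, 3.39 and 2.68. Iglv1 was 5.80 without CAC tumour 1 and Pfn2 -5.59 without CAC tumour 3. Without CAC control 1 the adjusted p was 0.0916 for Tifa, 0.0722 for Dach2, 0.056 for Hba-a1, 0.0727 for Mmp11, 0.131 for Vim, 0.114 for Xbp1, 0.123 for Spred2, 0.167 for Timp2 and 0.182 for Plk2, and without CAC control 2 it was 0.074 for Wdfy1, 0.158 for Phlda1 and 0.126 for Kit.

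Probe sets with several gene symbols were not used in the comparisons. Of 831, 506 were above the intensity filter, and 206 were higher in CAC tumours and 182 in sporadic tumours than in their controls, with 88 and 108 lower. Among them 11 immunoglobulin probe sets had a median log2 fold change of 6.668 in CAC tumours, with 11 higher, and of 4.594 in sporadic tumours, with 7 higher. With limma 0 of 11 passed in the difference, where the median was 2.243 and 6 had an unadjusted p under 0.05. Between the tumours 10 of 11 were higher in CAC, with a median of 3.293.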

How the results depend on the processing

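Leaving out CAC tumours 1 and 4 together was chosen after the results were seen; the other settings were not. The counts of genes in both tumour comparisons stayed within 1.5 times under every setting except the stricter fold rule, and the overlap of the effects under every setting run for it, which left out the stricter thresholds and fits of the compared groups only. Except where a setting tests fewer genes, uses fewer samples or adds a condition, the cause was not tested.

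With a log2 fold change of at least 1, the counts were 2256 for CAC, 2746 for sporadic, 656 between tumours and 570 between controls. At an adjusted p of 0.01 they were 87 for the difference, 957 between tumours and 415 between controls. The difference had 639 genes with median centring, 1014 without the intensity filter and 206 with the replicate number as a block, and the control comparison had 1919 without the filter. With that block, 11 of the 24 calls of named genes in the difference ended, with adjusted p from 0.0512 for Lmo2 to 0.114 for Kit, the others being Plk2, Phlda1, Pyy, Mmp11, Xbp1, Dach2, Dkk2, Spred2 and Timp2. In the difference 10 also ended without CAC tumours 1 and 4 (0.0585 to 0.109), 4 with quantile normalization (0.0541 to 0.0869), and 1 or 2 with each of 5 other settings. Of 59 between tumours, 28 ended without CAC tumours 1 and 4 (0.0517 to 0.392), 18 in fits of the compared groups only (0.0518 to 0.113), 17 without the filter (0.0506 to 0.102) and 16 with the replicate block (0.0504 to 0.122), and 7 or fewer with each other setting. At most 10 of 86 ended in CAC, 5 of 99 in sporadic tumours and 9 of 32 between controls under any of these settings. The replicate numbers did not pair samples, with correlations of deviations from -0.086 to 0.07.

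With single samples left out, counts ran from 2769 to 3704 for CAC, 4342 to 4749 for sporadic, 170 to 474 for the difference, 1502 to 1904 between tumours, 514 to 956 between controls and 2410 to 3057 for the overlap. The lowest counts for the difference and the controls came without CAC control 1.

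The number of lists past camera was 13, 13, 2, 5 and 2 in the order of the comparisons. With an estimated correlation it was 4, 0, 0, 0 and 0, with 7, 5, 0, 1 and 1 at an unadjusted p under 0.05. With fry it was 0 for the difference, 3 between tumours and 0 between controls. For the difference it was 1 with quantile normalization, with the filter above 6, with the mean of all probe sets and with array weights, and 0 without the filter. Between tumours it was 3 without the filter and with the mean of all probe sets, and 8 with the replicate block. Between controls it was 1 without the filter. With single samples left out it ran from 13 to 14 for CAC, 13 to 13 for sporadic, 0 to 4 for the difference, 4 to 8 between tumours and 2 to 3 between controls.

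Values that changed sign were all of results not past the threshold. The p53 list median in CAC was -0.189 with quantile normalization, -0.087 with median centring, -0.007 with array weights, -0.031 with the replicate block, -0.053 to 0.162 with single samples left out and -0.089 without CAC tumours 1 and 4. In sporadic tumours it was 0.052 with the filter above 6. The interferon list median in sporadic tumours was -0.046 with quantile normalization, -0.119 with median centring, -0.004 with array weights and -0.011 (without sporadic tumour 2) to 0.381 with single samples left out. In CAC it ran from -0.069 to 0.645 with single samples left out. The squamous list median in sporadic tumours was 1.01 with the mean of all probe sets and 0.352 with the replicate block. Myc was 0.005 between tumours with quantile normalization, and with median centring 0.037 in the difference and -0.062 between controls. With the mean of all probe sets Xbp1 was -0.007 in CAC and Ptgs2 0.005 between controls. Apc in CAC was -0.037 without CAC tumours 1 and 4.

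With single samples left out, Apc in CAC ran from -0.012 (without CAC control 1) to 0.283. S100a8 without CAC tumour 1 was -0.425 in the difference and -0.158 between tumours, where the highest values were 1.55 and 1.817. In the difference Myc ran from -0.233 to 0.072 (without sporadic control 3). Between controls Myc ran from -0.159 (without sporadic control 3) to 0.147, with -0.059 without CAC control 2. Without CAC control 2 the control comparison gave -0.115 for Pla2g2a, up to 1.0 with others left out, -0.111 for Gpm6b, up to 0.548, and -0.077 for Tnf, up to 0.792. Ereg there ran from -0.249 to 0.236 (without CAC control 2), with 0.111 without sporadic control 2, and Egfr from -0.052 (without sporadic control 2) to 0.538.

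Signal over background limits the low end. Without the filter, 1785 of the 5085 genes below it were called in CAC, 1775 of them lower, with a median size of 0.319 on the log2 scale, and 1697 in sporadic tumours, 1634 of them lower, with a median size of 0.263.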
